A study of Mus musculus with 14 samples.

How the data were processed

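The measurements are from 14 microarrays of the mouse line BH1-Bcl2-Ik1ER, in 7 groups with 2 arrays each. The groups and the experiment number of each array were taken from the sample titles. Per the labels' protocols, biotin-labelled single-stranded DNA targets were prepared from 150 ng of total RNA with Ambion and Affymetrix whole-transcript kits. The submitters' processing notes name Affymetrix Expression Console 1.1 and RMA, a method that corrects background, normalizes arrays by quantiles and summarises probes. The authors deposited 1 table of log2 values for 35556 probe sets, which was used as deposited with no further scaling. Further settings of that processing, the genome build and the annotation are not given in the sources used here. No scanner intensities were used here, so the limits of detection and saturation were not read from the arrays. RMA assumes that most genes do not change between arrays, so changes are relative to the bulk of the genes. The median log2 change of all genes lay between -0.037 and 0.058 in the 9 comparisons, and renewed quantile normalization shifted it by -0.076 at most.

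Probe sets were named through the probe annotation. Of the 35556 probe sets 23410 were listed with a gene, 21789 with 1 symbol and 1621 with several, and 12146 were unlisted and stayed unnamed. Names were checked against the RefSeq gene table, which held no newer symbol for any probe and lacked the gene identifiers of 91 probes. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over all arrays was used, which left 19938 genes. Probe sets with several symbols or none entered no gene comparison. Members of a gene list without a probe set of their own were not analysed here.

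Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit over all 14 arrays with a mean per group, which left 7 residual degrees of freedom plus 4.83 prior degrees. The 9 comparisons were 6 h of culture with 4OHT against time 0, IL-7 withdrawal at 6 h, 24 h of culture against time 0, 4OHT at 24 h with and without IL-7, IL-7 withdrawal at 24 h with and without 4OHT, the interaction of the treatments at 24 h, and both treatments against neither. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all 19938 genes, with no fold minimum. Tests were two-sided. With 2 arrays per group the spread was pooled over groups and genes. The 2 arrays of each group come from 2 independent experiments in 1 cell line. The p-values rest on the spread between arrays of a group, which includes shifts that all arrays of an experiment share. They do not directly measure how a treatment effect varies between experiments.

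The experiment number pairs the arrays, since the labels give the 2 numbers as independent experiments. Deviations of same-numbered arrays from their group means correlated positively in all 21 pairs of groups (0.124 to 0.631, median 0.392), and 3731 genes differed between the experiments. The fit without the experiment as a block was the chosen design, and blocked values stand beside total counts and counts of a called list's passing members that they moved by over 1.5-fold, and beside list calls they changed. The block made 60 of the named gene results pass and ended none. No 2 arrays of a group held identical values.

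The 29 gene lists covered B cell stages (pro-B and large pre-B markers, small pre-B and later B cell markers, immunoglobulin light chain loci, V(D)J recombination, pre-B cell receptor signalling, B lineage transcription factors), signalling (IL-7 and STAT5 response, FoxO targets, interferon response, NF-kappaB response, Notch targets, immediate early genes), the cell cycle and survival (DNA replication, G2/M, cyclin-dependent kinase inhibitors, p53 targets, BCL2 family), metabolism and protein quality (glycolysis, cholesterol and fatty acid synthesis, ribosome biogenesis and MYC targets, ATF4 and amino acid response, heat shock proteins), integrins and adhesion, MHC class II presentation, and markers of T, myeloid, erythroid and megakaryocyte, plasma and stromal cells. Some genes stand in more than 1 list. The cyclin-dependent kinase inhibitor list also holds Rb1, Rbl1 and Rbl2, which are not such inhibitors. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 261 tests, with an estimated correlation and fry beside it. Overlaps between comparisons were tested with two-sided Fisher's exact tests, in pairs of comparisons with no common array. All comparisons still take each gene's spread from the same fit. Genes with a small spread pass more readily in each of them, so overlaps in any direction can exceed those of independent lists.

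The named genes are, per comparison, the 6 largest rises and 6 largest falls among genes that passed, moved the same way in both experiments and lay above the median of all probes in the higher group, without predicted genes, immunoglobulin variable segments, olfactory receptors, microRNAs and small nucleolar RNAs. To these come 20 fixed genes (such as Ikzf1, Myc, Ccnd2, Cish, Bcl6, Foxo1, Rag1 and Vpreb1) and up to 4 members with the smallest p of each called list. The groups, tests, lists, named-genes rule and the alternatives below were set before the data were examined. These alternatives were the experiment as a block, a filter that kept 11003 genes above the array median in at least 2 arrays, an intensity trend with robust variances, a fit on the compared arrays only, the mean of all probes of a gene, quantile normalization, a minimum of 1.5-fold, an estimated correlation for lists and leaving out each array in turn. Chosen after the data were seen were the 24 h arrays with IL-7 and no 4OHT as reference for 6 h with 4OHT, and fits without the time 0 arrays.

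The fit was tested on simulated data for 4OHT at 24 h with IL-7, with 200 of 19938 genes changed. It called 40 of 50 genes changed by 0.5 on the log2 scale, 48 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 3. The simulation gave 14 false calls, 6.9% of its calls. Its spread was drawn independently for each gene and array, without the deviations that real arrays of 1 experiment share. It also changed fewer genes than the 1826 called in that comparison, so 6.9% is not an error rate for these data. Figures were drawn with matplotlib 3.10.9 from tables read with pandas 2.3.3.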

Results

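Gene expression was measured on microarrays in BH1-Bcl2-Ik1ER cells, a mouse pre-B cell line that is deficient in Ikaros. Ikaros is a zinc finger transcription factor of lymphoid cells encoded by Ikzf1. The line carries retroviruses for Bcl2, a protein that blocks apoptosis, and for a fusion of Ikaros to the estrogen receptor whose activity is induced with 4-hydroxytamoxifen (4OHT, 100 nM). The cells grow with IL-7, the cytokine that supports early B cells, supplied here as 8% conditioned medium, and withdrawal meant culture without that medium. The 14 arrays fell into 7 groups of 2 arrays, 1 from each of 2 independent experiments. The groups were time 0, 6 h with 4OHT and with or without IL-7, and 24 h with or without 4OHT and with or without IL-7. Array medians lay between 7.23 and 7.43 on the log2 scale, and the 2 arrays of a group correlated at 0.9968 to 0.9982. The number of arrays limits the precision, with a median standard error (SE) of 0.091 for a log2 difference. The series asks which genes Ikaros and IL-7 control in these cells. No cells without the fusion were measured, so effects of 4OHT itself are not separated from those of Ikaros activity in any comparison. Changes are log2 differences ± SE with n = 2 arrays per group throughout, tested with limma.

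Ikzf1 itself was read at 13.12 ± 0.10 (SD, n = 2) at time 0 and at 13.34 ± 0.05 (SD, n = 2) after 24 h with 4OHT and without IL-7. The probe positions were not available, so it is open whether its probe reads the endogenous transcript, the transduced fusion or both. The Ikzf1 signal therefore does not check the labels. Ikzf1 passed the test after 24 h without IL-7, by 0.23 ± 0.07 without 4OHT (adjusted p = 0.0357) and 0.25 ± 0.07 with it (adjusted p = 0.0239). It also passed under both treatments at 24 h (0.30 ± 0.07, adjusted p = 0.00473), and neither at 6 h with 4OHT against time 0 nor for 4OHT at 24 h. Bcl2 was read at 8.30 ± 0.02 (SD, n = 2) at time 0 and passed in no comparison. Rag1 and Rag2, the recombinase of antigen receptor genes, Il2ra and Cd2, surface markers of small pre-B cells, and Kit, a receptor of earlier precursors, lay below the median of 7.33 over all values in every group and passed in no comparison. With the experiment as a block Kit passed for 4OHT at 24 h with IL-7 (-0.29, limma adjusted p = 0.0144). At time 0 Rag1 was read at 5.74 ± 0.12 and Il2ra at 5.48 ± 0.05 (SD, n = 2). Natural killer cell markers were not among the lists tested. The lists for T cells, myeloid cells, erythroid cells and megakaryocytes, plasma cells and stromal cells were called in none of the 9 comparisons, with smallest camera adjusted p-values of 0.0854, 0.0817, 0.126, 0.248 and 0.0824. The Notch target list was called in none either, with a smallest adjusted p of 0.493.

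**Figure D1:**
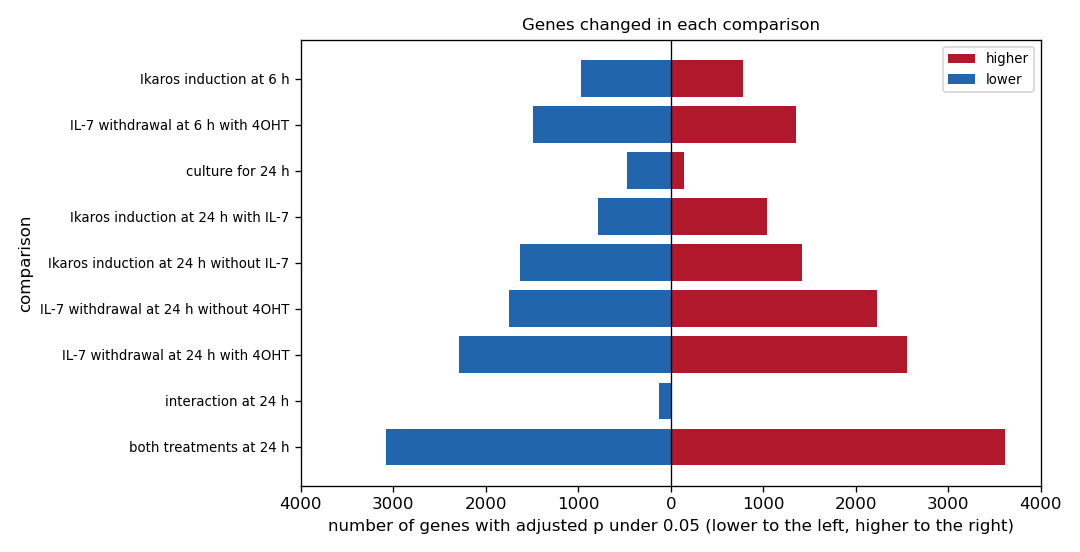
Number of genes with a limma adjusted p under 0.05 in each comparison, with genes that fell to the left of 0 and genes that rose to the right. The counts run from 137 genes for the interaction to 6690 genes for both treatments together at 24 h.

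With IL-7 kept, 6 h of culture with 4OHT went with higher levels of cytokine response genes and lower levels of sterol synthesis genes than at time 0. Mpzl2, an adhesion molecule, rose by 3.04 ± 0.29 (adjusted p = 4.45e-05). Cxcr5, a chemokine receptor of B cells, rose by 2.97 ± 0.17 (adjusted p = 9.77e-07), and Cish, a feedback inhibitor induced by STAT5, rose by 2.45 ± 0.09 (adjusted p = 4.67e-08). The other largest rises were Lfng (2.09 ± 0.16), which encodes a glycosyltransferase that modifies Notch, Zc3h12d (1.94 ± 0.12) and Epb41l4b (1.80 ± 0.14). The largest falls were in 3 of the guanylate-binding protein genes, Gbp11 (-3.40 ± 0.15), Gbp8 (-3.11 ± 0.17) and Gbp4 (-2.91 ± 0.21), in Nlrp3 (-2.52 ± 0.11), an inflammasome sensor, in the repressor gene Bcl6 (-2.38 ± 0.09) and in Nr4a1 (-2.24 ± 0.11), an orphan nuclear receptor. Because no array at 6 h without 4OHT is among the labelled groups, 6 h of culture and 4OHT are not separated in this comparison.

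Of the 15 genes of the IL-7 and STAT5 response list, 11 rose and 1 fell (12 and 1 adjusted over the list alone), among them Cish, Socs2 (1.54 ± 0.12) and Mycn (1.24 ± 0.09). This list was called with camera's preset correlation (adjusted p = 5.39e-13) and also with an estimated correlation (adjusted p = 0.022). Ribosome biogenesis and MYC target genes rose at 12 of 20 members (19 adjusted over the list alone), such as Rrp9 (1.05 ± 0.13) and Polr1b (0.87 ± 0.10). Ribosome biogenesis had a camera adjusted p = 4.63e-18, or adjusted p = 0.244 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell at 14 of 17 members (17 adjusted over the list alone), such as Cyp51 (-1.29 ± 0.14), Sqle (-1.16 ± 0.13) and Fdps (-0.93 ± 0.09). Lipid synthesis genes had a camera adjusted p = 5.84e-19, or adjusted p = 0.235 with an estimated correlation. Of 12 pro-B and large pre-B markers 5 fell (5 adjusted over the list alone), including the transcription factor Lef1 (-1.03 ± 0.09) and Vpreb1 (-0.84 ± 0.08), a chain of the surrogate light chain. Pro-B and large pre-B markers had a camera adjusted p = 0.00557, or adjusted p = 0.261 with an estimated correlation. Integrin and adhesion genes fell at 6 of 17 members and rose at 1 (7 and 2 adjusted over the list alone), led by Itga5 (-1.42 ± 0.11) and Ctnnd1 (-1.01 ± 0.08). Integrin and adhesion genes had a camera adjusted p = 0.000338, or adjusted p = 0.235 with an estimated correlation. Immediate early genes fell at 2 of 12 members (4 adjusted over the list alone), Nr4a1 and Klf4 (-0.37 ± 0.09). Immediate early genes had a camera adjusted p = 0.0028, or adjusted p = 0.235 with an estimated correlation. DNA replication genes lay lower by a mean of -0.30 (camera adjusted p = 0.000169, or adjusted p = 0.597 with an estimated correlation), with 1 of the 24, Chaf1a (-0.51 ± 0.13), passing limma's test (0 adjusted over the list alone, 9 at an unadjusted p under 0.05). The BCL2 family had 2 of 12 higher and 1 lower (5 and 1 adjusted over the list alone), with Bcl2l11 (0.63 ± 0.08) and Bcl2l1 (0.68 ± 0.16) up and Pmaip1 (-0.52 ± 0.08) down. The BCL2 family had a camera adjusted p = 0.0311, or adjusted p = 0.308 with an estimated correlation. MHC class II genes were higher at 3 of 8 members (3 adjusted over the list alone), among them Cd74 (0.80 ± 0.21). MHC class II genes had a camera adjusted p = 0.0495, or adjusted p = 0.344 with an estimated correlation. The experiment as a block raised the passing members to 8 of 24 DNA replication genes, 5 of 12 immediate early genes and 5 higher and 1 lower of the BCL2 family, and to 19 of 20 ribosome biogenesis genes.

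In limma's test 1748 of 19938 genes passed at 6 h, 781 higher and 967 lower, and all 1748 moved the same way in both experiments. A gene with opposite changes in the 2 experiments could hardly pass, so the selection itself largely ensures this agreement. With the experiment number as a block 2999 genes passed, 1362 higher and 1637 lower, and the G2/M and mitosis list, which was not called without the block (adjusted p = 0.0807), was then called lower (adjusted p = 0.00886). Leaving out the array at 6 h with 4OHT and IL-7 of experiment 1 left 1067 genes, and leaving out the time 0 array of experiment 2 left 1160. Against the 24 h arrays with IL-7 and no 4OHT in place of time 0, a reference chosen after the data were seen, 1652 genes passed, 971 higher and 681 lower, and 837 of the 1748 kept their call and direction. In that comparison Ccnd2, the cyclin D2 gene, went from 1.06 ± 0.19 to a value of -0.297 that did not pass (adjusted p = 0.411). Against that reference Socs2 (0.277, adjusted p = 0.198), Cd74 (0.624, adjusted p = 0.0975) and Klf4 (-0.299, adjusted p = 0.0778) did not pass either, and the immediate early list was not called (adjusted p = 0.174). Without dim genes the BCL2 family and MHC class II lists were not called (adjusted p of 0.102 and 0.0808), nor was MHC class II on the compared arrays only (adjusted p = 0.0558).

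IL-7 withdrawal for 6 h, with 4OHT present, lowered genes of the IL-7 and STAT5 response and of ribosome biogenesis and MYC targets. Srm, spermidine synthase, changed by -3.29 ± 0.15 on the log2 scale (adjusted p = 1.4e-07), Dctd, the deoxycytidylate deaminase gene, by -3.05 ± 0.12 (adjusted p = 4.65e-08) and Cish by -2.99 ± 0.09 (adjusted p = 4.54e-09). Cxcr5 (-2.87 ± 0.17), Ccnd2 (-2.72 ± 0.19) and Car12 (-2.45 ± 0.17), a carbonic anhydrase, followed, and Myc fell by 2.13 ± 0.11. Bcl6 rose by 2.48 ± 0.09 (adjusted p = 2.92e-08), above the integrin gene Itga1 (1.49 ± 0.13), the potassium channel gene Kcnj2 (1.38 ± 0.10), Tmtc1 (1.27 ± 0.14), Cpm (1.26 ± 0.24), a membrane carboxypeptidase, and the growth factor receptor gene Fgfr2 (1.21 ± 0.10).

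Ribosome biogenesis and MYC target genes fell at 19 of 20 members (20 adjusted over the list alone), among them Polr1b (-2.44 ± 0.10), a subunit of RNA polymerase I, and Bop1 (-1.64 ± 0.09). Ribosome biogenesis gave a camera adjusted p = 1.32e-35, or adjusted p = 0.235 with an estimated correlation. Of the IL-7 and STAT5 response list 10 of 15 fell and 2 rose (11 and 2 adjusted over the list alone), and this call held with an estimated correlation. The IL-7 list had a camera adjusted p = 4.16e-09, or adjusted p = 0.0364 with an estimated correlation. FoxO target genes rose at 8 of 21 members and fell at 1 (10 and 2 adjusted over the list alone), including Cdkn1b (0.61 ± 0.10) and Ccng2 (0.65 ± 0.11). FoxO targets had a camera adjusted p = 0.000338, or adjusted p = 0.369 with an estimated correlation. The cyclin-dependent kinase inhibitor list had 3 of 9 members higher (4 adjusted over the list alone), Cdkn2d (0.86 ± 0.12), Cdkn1b and Rb1 (0.55 ± 0.08). Kinase inhibitors had a camera adjusted p = 0.00418, or adjusted p = 0.303 with an estimated correlation. Glycolysis genes fell at 5 of 16 members (8 adjusted over the list alone), led by Hk2 (-1.54 ± 0.11). Glycolysis had a camera adjusted p = 0.000688, or adjusted p = 0.435 with an estimated correlation. ATF4 and amino acid response genes fell at 6 of 14 members and rose at 1 (6 and 2 adjusted over the list alone), led by the transporter gene Slc7a5 (-2.35 ± 0.16). ATF4 genes had a camera adjusted p = 0.0017, or adjusted p = 0.338 with an estimated correlation. Heat shock protein genes fell at 4 of 8 members and rose at 1 (5 and 1 adjusted over the list alone), with Hspd1 at -1.59 ± 0.13. Heat shock genes had a camera adjusted p = 0.00347, or adjusted p = 0.404 with an estimated correlation.

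Lists of B cell maturation were called higher at 6 h without IL-7 as well, on few members each. The small pre-B and later B cell markers had 2 of 19 members higher (1 adjusted over the list alone), Spib (0.68 ± 0.10), an Ets transcription factor, and Ikzf3 (0.34 ± 0.10), and pre-B cell receptor signalling had 3 of 12 higher (6 adjusted over the list alone), Blnk, Syk and Prkcb. Their camera adjusted p-values were 0.0152 and 0.0155, with an adjusted p of 0.392 and 0.366 with an estimated correlation. The B lineage transcription factors had 4 of 22 higher (5 adjusted over the list alone). B lineage factors had a camera adjusted p = 0.0146, or adjusted p = 0.404 with an estimated correlation. NF-kappaB response genes had 2 of 11 higher, Nfkb2 (0.37 ± 0.07) and Tnfaip3 (0.41 ± 0.10) (4 adjusted over the list alone, camera adjusted p = 0.0458, or adjusted p = 0.327 with an estimated correlation), and with the experiment as a block the list was no longer called (adjusted p = 0.071). The 2 cell cycle lists went opposite ways. DNA replication genes were lower by a mean of -0.15 (camera adjusted p = 0.023, or adjusted p = 0.757 with an estimated correlation), with Mcm6 (-0.85 ± 0.16) and Mcm2 (-0.65 ± 0.13) the 2 of 24 that fell (2 adjusted over the list alone). G2/M genes were higher by a mean of 0.23 (camera adjusted p = 0.0318, or adjusted p = 0.762 with an estimated correlation), with 0 of 21 passing limma's test and 6 at an unadjusted p under 0.05 (0 adjusted over the list alone). Passing members rose in number with the experiment as a block, to 7 of 21 G2/M genes, all higher, and 5 of 24 DNA replication genes, all lower. They were then 6 of 19 small pre-B and later markers, 6 of 12 pre-B cell receptor signalling genes and 5 of 9 in the kinase inhibitor list. The block also gave 8 higher and 1 lower of 22 B lineage factors, and 9 lower and 1 higher of 16 glycolysis genes.

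At 6 h without IL-7, 2844 of 19938 genes passed limma's test, 1352 higher and 1492 lower. All had the same direction in both experiments, as the selection by p largely ensures. At least 2-fold changes were mostly falls, 272 against 20 rises. Leaving out single arrays gave 1850 and 1840 genes for the arrays without IL-7 of experiments 1 and 2 and 1490 for the array with IL-7 of experiment 1. Without dim genes the DNA replication, G2/M and NF-kappaB lists were not called (adjusted p of 0.108, 0.0907 and 0.089), nor was DNA replication after quantile normalization (adjusted p = 0.0801).

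The 24 h arrays with IL-7 and no 4OHT served as a time control against time 0. In these, without 4OHT, Nrxn3, a neurexin gene, rose by 1.44 ± 0.27 (adjusted p = 0.0153), Ccnd2 by 1.36 ± 0.19 (adjusted p = 0.00463), Cish by 1.28 ± 0.09 (adjusted p = 4.02e-05) and Socs2 by 1.26 ± 0.12 (adjusted p = 0.000501), with Lfng (1.11 ± 0.16) and Epb41l4b (1.07 ± 0.14) next. Gbp4 (-2.28 ± 0.21), Gbp11 (-1.96 ± 0.15), Gbp8 (-1.74 ± 0.17), Gbp9 (-1.61 ± 0.20), Bcl6 (-1.35 ± 0.09) and Cpm (-1.30 ± 0.24) fell. Cholesterol and fatty acid synthesis genes fell at 12 of 17 members (14 adjusted over the list alone), among them Lss (-1.09 ± 0.16) and Nsdhl (-0.92 ± 0.10). Lipid synthesis genes gave a camera adjusted p = 6.37e-18, or adjusted p = 0.235 with an estimated correlation. Ribosome biogenesis genes rose at 8 of 20 members (17 adjusted over the list alone, camera adjusted p = 8.18e-15, or adjusted p = 0.255 with an estimated correlation), and the IL-7 and STAT5 list at 4 of 15 (5 adjusted over the list alone). The IL-7 list gave a camera adjusted p = 0.000786, or adjusted p = 0.235 with an estimated correlation.

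The remaining list calls at 24 h of culture rested on small shifts. DNA replication genes were higher by a mean of 0.39, with 0 of 24 passing limma's test over all genes (13 with the experiment as a block), 6 adjusted over the list alone and 18 at an unadjusted p under 0.05. G2/M genes were higher by 0.21 with 0 of 21 passing (2 with the block) and 0 at an unadjusted p under 0.05 in limma, and heat shock genes by 0.22 with 0 of 8 passing in limma (4 with the block, 3 adjusted over the list alone, 4 at an unadjusted p under 0.05). Camera gave adjusted p-values of 2.36e-10, 0.00242 and 0.01, with an adjusted p of 0.379, 0.667 and 0.457 with an estimated correlation. Glycolysis genes had 1 member higher, Hk2 (0.52 ± 0.11), and 1 lower, Aldoc (-0.84 ± 0.11), of 16 (5 and 1 adjusted over the list alone, camera adjusted p = 0.041 upward, or adjusted p = 0.656 with an estimated correlation). FoxO targets fell at 3 of 21 members, Bcl6, Sesn3 and Blnk (5 adjusted over the list alone). FoxO targets gave a camera adjusted p = 0.000322, or adjusted p = 0.369 with an estimated correlation. B lineage transcription factors fell at 2 of 22, Spib (-0.59 ± 0.10) and Irf8 (-0.33 ± 0.07) (2 adjusted over the list alone). B lineage factors gave a camera adjusted p = 0.00478, or adjusted p = 0.372 with an estimated correlation. Pre-B cell receptor signalling fell at 1 of 12, Blnk (2 adjusted over the list alone, camera adjusted p = 0.0391, or adjusted p = 0.392 with an estimated correlation), p53 targets at 1 of 13, Trp53inp1 (5 adjusted over the list alone, camera adjusted p = 0.0165, or adjusted p = 0.306 with an estimated correlation), and immediate early genes at Nr4a1 and Jun of 12 (2 adjusted over the list alone). Immediate early genes gave a camera adjusted p = 0.0441, or adjusted p = 0.303 with an estimated correlation. Integrin genes, with 0 of 17 passing in limma (3 lower and 1 higher with the block) and 7 at an unadjusted p under 0.05 (6 lower and 1 higher), and interferon response genes, with 0 of 15 passing (2 lower with the block) and 3 at an unadjusted p under 0.05, were called lower with camera adjusted p-values of 0.0173 and 0.0427 and an adjusted p of 0.308 and 0.721 with an estimated correlation. Adjusted over the list alone, 5 integrin genes were lower and 1 higher, and 1 interferon response gene was lower. The block also raised the passing members to 17 of 20 ribosome biogenesis genes, 6 higher and 1 lower of 16 glycolysis genes, 6 of 21 FoxO targets, 4 of 22 B lineage factors, 4 of 13 p53 targets and 2 of 12 pre-B cell receptor signalling genes.

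Over 24 h of culture 617 of 19938 genes passed limma's test, 147 higher and 470 lower, and 2056 with the experiment as a block, 630 higher and 1426 lower. After quantile normalization of the deposited values the split was 250 higher and 319 lower. The count rested on single arrays. It was 39 without the 24 h array of experiment 2 and 79 without the time 0 array of experiment 2. Without dim genes 6 lists were not called, with an adjusted p of 0.218 for pre-B cell receptor signalling, 0.0962 for p53 targets, 0.0962 for B lineage factors, 0.156 for integrins, 0.106 for interferon response and 0.376 for immediate early genes. Pre-B cell receptor signalling was not called on the compared arrays only either (adjusted p = 0.0502). Glycolysis was not called with the mean of all probes (adjusted p = 0.103) or after quantile normalization (adjusted p = 0.0601).

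At 24 h with IL-7, 4OHT raised a part of the genes of B cell maturation and lowered a part of the pro-B markers and adhesion genes. Cpm rose by 3.12 ± 0.24 (adjusted p = 6.55e-06), Fcrla, an Fc receptor-like protein of B cells, by 2.78 ± 0.14 (adjusted p = 3.8e-07) and Spib by 2.51 ± 0.10 (adjusted p = 6.76e-08). Klrb1 (2.56 ± 0.47), a lectin-like receptor known from natural killer cells, Ifi209 (2.23 ± 0.20), an interferon-inducible gene, and Rubcnl (2.15 ± 0.11) also rose. Igfbp7, a secreted binding protein for growth factors, changed by -3.26 ± 0.18 on the log2 scale (adjusted p = 7.53e-07) and Dock9, a guanine nucleotide exchange factor, by -2.72 ± 0.13 (adjusted p = 3.43e-07), followed by Nr4a1 (-2.33 ± 0.11), the creatine kinase gene Ckmt1 (-2.25 ± 0.34) and the non-coding RNA Lncenc1 (-2.21 ± 0.14).

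FoxO targets rose at 10 of 21 members (13 adjusted over the list alone), led by S1pr1 (2.05 ± 0.13), the sphingosine phosphate receptor, and Foxo1 itself rose by 0.82 ± 0.12. FoxO targets reached a camera adjusted p = 1.85e-10, or adjusted p = 0.235 with an estimated correlation. Pre-B cell receptor signalling rose at 6 of 12 (8 adjusted over the list alone), such as Prkcb (0.88 ± 0.11), Cd79a (0.66 ± 0.09) and Blnk (0.65 ± 0.09). Pre-B cell receptor signalling had a camera adjusted p = 1.56e-06, or adjusted p = 0.235 with an estimated correlation. Small pre-B and later B cell markers rose at 6 of 19 (7 adjusted over the list alone), among them Spib, Tnfrsf13c (1.27 ± 0.13), the BAFF receptor, and Cd22 (0.60 ± 0.08). Small pre-B and later markers had a camera adjusted p = 5.51e-06, or adjusted p = 0.244 with an estimated correlation. B lineage transcription factors rose at 9 of 22 and fell at 3 (11 and 3 adjusted over the list alone), with Tcf3 at 0.70 ± 0.07 and Pou2af1 at 0.51 ± 0.06. B lineage factors reached a camera adjusted p = 8.14e-06, or adjusted p = 0.249 with an estimated correlation. Immunoglobulin light chain probes rose at 3 of 8 (4 adjusted over the list alone), led by Igkv10-96 (2.58 ± 0.24). Light chain probes had a camera adjusted p = 0.000588, or adjusted p = 0.235 with an estimated correlation. In the V(D)J recombination list 3 of 11 rose (4 higher and 2 lower adjusted over the list alone), the end-joining genes Lig4 (1.40 ± 0.12), Xrcc4 (0.53 ± 0.12) and Xrcc6 (0.51 ± 0.09). V(D)J recombination had a camera adjusted p = 0.0384, or adjusted p = 0.344 with an estimated correlation. The kinase inhibitor list rose at 2 of 9 (2 adjusted over the list alone), Cdkn1b (0.70 ± 0.10) and Rb1 (0.66 ± 0.08). Kinase inhibitors gave a camera adjusted p = 0.0077, or adjusted p = 0.31 with an estimated correlation.

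Pro-B and large pre-B markers fell at 4 of 12 members at 24 h with IL-7 (8 lower and 1 higher adjusted over the list alone), Lef1 (-0.70 ± 0.09), Spn (-0.66 ± 0.08), Vpreb1 (-0.59 ± 0.08) and Vpreb2 (-0.51 ± 0.08). Pro-B and large pre-B markers gave a camera adjusted p = 0.000642, or adjusted p = 0.235 with an estimated correlation. Integrin and adhesion genes fell at 5 of 17 and rose at 2 (8 and 2 adjusted over the list alone), with Itga5 (-1.27 ± 0.11), Cd9 (-1.13 ± 0.10) and Ctnnd1 (-1.05 ± 0.08) lower and Itga4 (0.83 ± 0.12) higher. Integrin and adhesion genes gave a camera adjusted p = 0.0199, or adjusted p = 0.317 with an estimated correlation. Immediate early genes fell at 3 of 12, Nr4a1, Ier2 and Ier3 (3 adjusted over the list alone). Immediate early genes reached a camera adjusted p = 0.0201, or adjusted p = 0.255 with an estimated correlation. Cish fell by 0.88 ± 0.09, while Myc (-0.23 ± 0.11, adjusted p = 0.221) and Ccnd2 (-0.52 ± 0.19, adjusted p = 0.119) did not pass. With the experiment as a block Ccnd2 passed (adjusted p = 0.00118). Of the 19938 genes, 1826 passed limma's test, 1041 higher and 785 lower, and the split was 824 higher and 1125 lower after quantile normalization. With the experiment as a block 3324 passed, 1813 higher and 1511 lower, and the glycolysis list was then called lower (adjusted p = 0.0389, against 0.0851 without the block). The count was 847 without the array with 4OHT of experiment 1 and 1006 without the array lacking 4OHT of experiment 2. The block raised the passing members to 7 of 12 pro-B and large pre-B markers, all lower, 9 lower and 2 higher of 17 integrin genes and 4 higher and 2 lower of 11 V(D)J recombination genes. Without dim genes the V(D)J recombination and kinase inhibitor lists were not called (adjusted p of 0.0536 and 0.0971), and on the compared arrays only the integrin list was not (adjusted p = 0.0532).

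**Figure D2:**
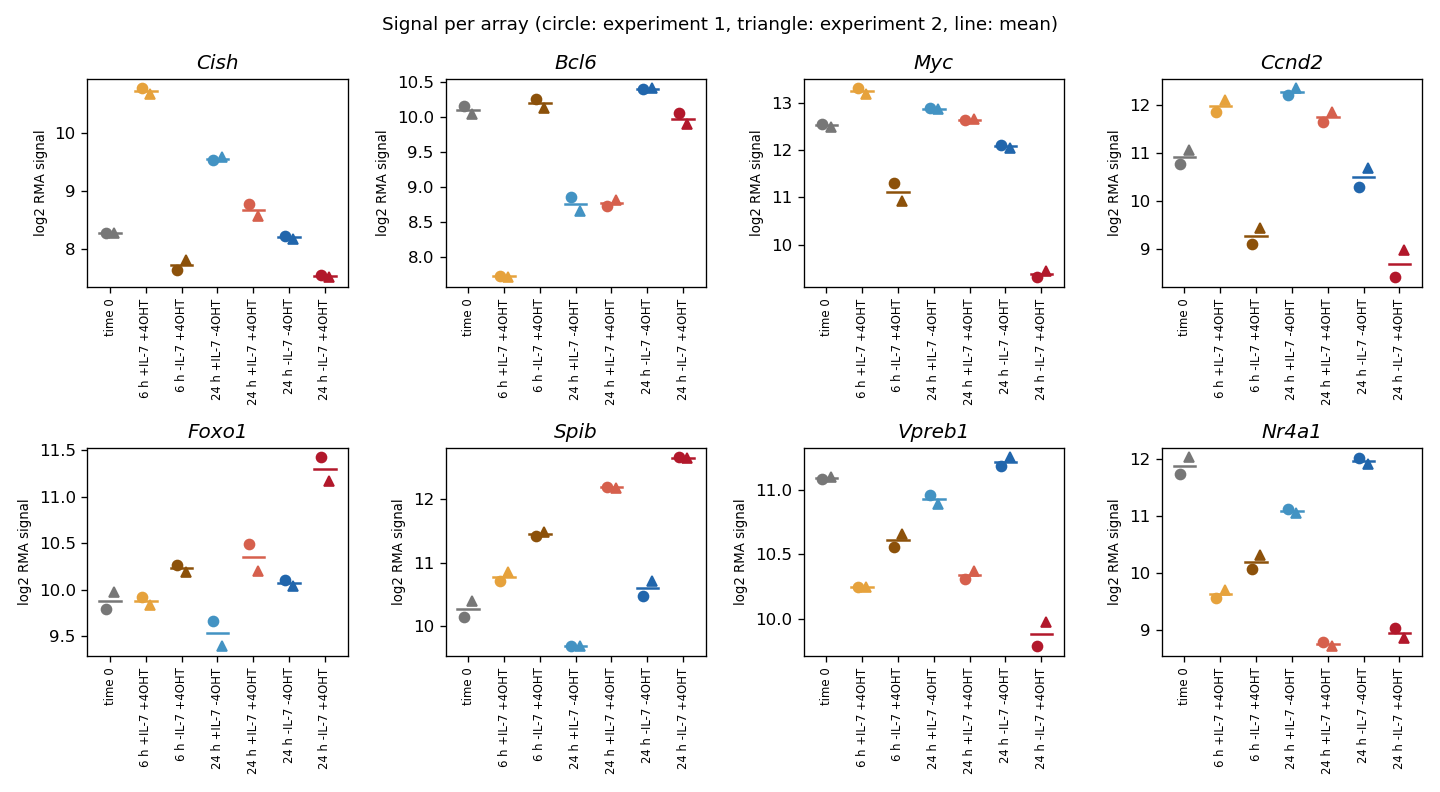
Log2 signal of 8 genes in each of the 14 arrays by group, with circles for experiment 1, triangles for experiment 2 and lines for the mean of 2 arrays. Myc fell by 2.70 under 4OHT at 24 h without IL-7 and did not pass with IL-7 (-0.23), whereas Spib rose under 4OHT in both.

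At 24 h without IL-7, 4OHT changed many of the same genes and in addition lowered Myc and ribosome biogenesis genes. Eqtn, known as a sperm acrosome protein, rose by 3.53 ± 0.33 (adjusted p = 1.58e-05), Klrb1 by 3.33 ± 0.47 (adjusted p = 0.000322), Cpm by 2.88 ± 0.24 (adjusted p = 5.01e-06), Ifi209 by 2.76 ± 0.20, Ralgps2 by 2.72 ± 0.14 and S1pr1 by 2.54 ± 0.13. Slc7a11, the cystine transporter, changed by -3.30 ± 0.79 on the log2 scale (adjusted p = 0.0124) and Dock9 by -3.16 ± 0.13 (adjusted p = 1.76e-08), with Igfbp7 (-3.01 ± 0.18), Nr4a1 (-3.01 ± 0.11) and Nlrp3 (-2.98 ± 0.11) next. Myc changed by -2.70 ± 0.11, Ccnd2 by -1.80 ± 0.19 and Vpreb1 by -1.34 ± 0.08, and Foxo1 rose by 1.22 ± 0.12.

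Ribosome biogenesis and MYC target genes fell at 16 of 20 members (17 adjusted over the list alone), led by Srm (-2.39 ± 0.15) and Polr1b (-1.71 ± 0.10). Ribosome biogenesis reached a camera adjusted p = 1.32e-16, or adjusted p = 0.249 with an estimated correlation. DNA replication genes fell at 11 of 24 (15 adjusted over the list alone), such as Tyms (-1.04 ± 0.17) and Mcm2 (-0.83 ± 0.13). DNA replication genes had a camera adjusted p = 5.89e-08, or adjusted p = 0.435 with an estimated correlation. Heat shock genes fell at 5 of 8 (5 adjusted over the list alone), with Hsph1 at -1.44 ± 0.12. Heat shock genes gave a camera adjusted p = 0.000499, or adjusted p = 0.366 with an estimated correlation. Glycolysis genes fell at 7 of 16 and rose at 1 (9 and 1 adjusted over the list alone), with Pgk1 (-1.01 ± 0.16) lower and the lactate transporter gene Slc16a1 (0.90 ± 0.14) higher. Glycolysis gave a camera adjusted p = 0.00153, or adjusted p = 0.465 with an estimated correlation. ATF4 and amino acid response genes fell at 7 of 14 (7 adjusted over the list alone), among them Slc7a5 (-1.17 ± 0.16), Phgdh (-1.15 ± 0.19) and Asns (-1.11 ± 0.19). ATF4 genes gave a camera adjusted p = 0.00272, or adjusted p = 0.353 with an estimated correlation.

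FoxO targets and the lists of B cell maturation moved under 4OHT without IL-7 too, except V(D)J recombination, which was not called there. That list was called higher only after quantile normalization (camera adjusted p = 0.049). FoxO targets rose at 11 of 21 and fell at 2 (14 and 2 adjusted over the list alone), pre-B cell receptor signalling rose at 7 of 12 (8 adjusted over the list alone) and small pre-B and later B cell markers at 6 of 19 (6 adjusted over the list alone), with Prkcb at 1.20 ± 0.11, Syk at 0.95 ± 0.10 and Tnfrsf13c at 1.78 ± 0.13. These lists had camera adjusted p-values of 8.6e-06, 2.41e-06 and 0.000458, with an adjusted p of 0.306, 0.235 and 0.303 with an estimated correlation. Light chain probes rose at 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.000104, or adjusted p = 0.235 with an estimated correlation), and B lineage transcription factors rose at 9 of 22 and fell at 4 (10 and 4 adjusted over the list alone). B lineage factors had a camera adjusted p = 0.0315, or adjusted p = 0.462 with an estimated correlation. Pro-B and large pre-B markers fell at 5 of 12 and rose at 1 (7 and 1 adjusted over the list alone), with Spn at -1.21 ± 0.08 and Vpreb2 at -0.99 ± 0.08. Pro-B and large pre-B markers reached a camera adjusted p = 0.000114, or adjusted p = 0.235 with an estimated correlation. Integrin genes fell at 8 of 17 and rose at 2 (8 and 2 adjusted over the list alone). Integrin and adhesion genes reached a camera adjusted p = 0.0028, or adjusted p = 0.253 with an estimated correlation. Immediate early genes fell at 5 of 12 and rose at 1 (5 and 1 adjusted over the list alone). Immediate early genes had a camera adjusted p = 0.0334, or adjusted p = 0.292 with an estimated correlation.

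Without IL-7, 3045 of 19938 genes passed limma's test under 4OHT, 1416 higher and 1629 lower. Leaving out the arrays without 4OHT of experiments 1 and 2 gave 1841 and 2006 genes. With the experiment as a block the immediate early list was no longer called (adjusted p = 0.0508), while the G2/M list (adjusted p = 0.00937, against 0.0799 without the block) and the kinase inhibitor list (adjusted p = 0.0407, against 0.0593) were called higher. With the block 18 of the 24 DNA replication genes fell. Without dim genes the B lineage factor and immediate early lists were not called (adjusted p of 0.0808 and 0.145). Between the 4OHT effects with and without IL-7, which share no array, 842 genes rose in both against 73.9 for independent lists, and 600 fell in both against 64.1 (Fisher's exact test, odds ratios 135 and 57.2). The log2 changes correlated across genes at a Pearson r of 0.781, where genes are not independent replicates and arrays of one experiment deviate together.

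The interaction test asked directly whether the 4OHT effect at 24 h depended on IL-7. It passed for 137 of 19938 genes, 14 with a more positive and 123 with a more negative effect without IL-7, and for 449 with the experiment as a block, 82 and 367. Myc, the proto-oncogene of growth control, had the largest negative value (-2.47 ± 0.15, adjusted p = 3.05e-05), with 4OHT effects of -0.23 ± 0.11 with IL-7 and -2.70 ± 0.11 without. Srm (-2.37 ± 0.22, adjusted p = 0.000581) and Dctd (-2.16 ± 0.17, adjusted p = 0.000138) followed, then Nrp2 (-1.66 ± 0.11), a neuropilin gene, Ppa1 (-1.62 ± 0.26), the inorganic pyrophosphatase, and Vegfa (-1.59 ± 0.25). The largest positive values were in Adgrg1 (1.24 ± 0.21), an adhesion receptor gene, Nuggc (1.23 ± 0.13), Tfrc (1.14 ± 0.22), the transferrin receptor, Cd248 (1.12 ± 0.17), S100a10 (1.11 ± 0.14) and Zfp831 (0.92 ± 0.18). Of the 123 genes with a negative interaction 119 fell under 4OHT without IL-7, and 54 of these fell with IL-7 as well. Ccnd2 differed by -1.28 ± 0.27 but did not pass (adjusted p = 0.0587), whereas it passed with the experiment as a block (adjusted p = 0.00019). Leaving out any of 6 of the 8 arrays moved the count by over 1.5-fold. It was 74 without the array with 4OHT and without IL-7 of experiment 2, 59 and 55 without the arrays lacking both of experiments 1 and 2, 54 and 62 without the arrays with both, and 50 without the array with IL-7 alone of experiment 2.

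Among the lists, ribosome biogenesis and MYC targets had the most negative mean interaction (-0.71), with Srm, Polr1b (-1.48 ± 0.14), Nolc1 (-0.82 ± 0.15) and Polr1a (-0.77 ± 0.12) the 4 of 20 that passed (12 with the experiment as a block, 16 adjusted over the list alone). Ribosome biogenesis had a camera adjusted p = 4.48e-26, or adjusted p = 0.235 with an estimated correlation. The DNA replication list had a mean of -0.43 with 0 of 24 members passing in limma (4 with the block), 5 adjusted over the list alone and 11 at an unadjusted p under 0.05. DNA replication genes gave a camera adjusted p = 8.66e-11, or adjusted p = 0.372 with an estimated correlation. The heat shock list passed at 1 of 8, Hsph1 (-1.07 ± 0.17), the pro-B list at 1 of 12, Vpreb1 (-0.75 ± 0.11), and the IL-7 and STAT5 list at 1 of 15, Myc. These counts were 2, 4 and 2 adjusted over the list alone and 2, 3 and 2 with the block. Their camera adjusted p-values were 0.00314, 0.00419 and 0.0424, with an adjusted p of 0.402, 0.255 and 0.255 with an estimated correlation, and with the experiment as a block the IL-7 and STAT5 list was no longer called (adjusted p = 0.0508). ATF4 genes, with 0 of 14 passing in limma (3 lower with the block) and 4 at an unadjusted p under 0.05 (4 adjusted over the list alone), and glycolysis genes, with 0 of 16 passing (1 lower and 1 higher with the block) and 5 at an unadjusted p under 0.05 (4 lower and 1 higher, 0 adjusted over the list alone), had camera adjusted p-values of 0.00406 and 0.023 and an adjusted p of 0.366 and 0.617 with an estimated correlation. Not called in the interaction were FoxO targets, pre-B cell receptor signalling and small pre-B and later B cell markers. Their camera adjusted p-values were 0.545, 0.46 and 0.657. Without dim genes the IL-7 and STAT5, glycolysis and ATF4 lists were not called (adjusted p of 0.37, 0.17 and 0.0962), nor was the IL-7 and STAT5 list on the compared arrays only (adjusted p = 0.07) or after quantile normalization (adjusted p = 0.101).

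IL-7 withdrawal for 24 h without 4OHT lowered cell cycle genes. Fancd2, of the Fanconi anaemia DNA repair pathway, changed by -2.46 ± 0.24 on the log2 scale (adjusted p = 3.49e-05), Ncapg, a condensin subunit, by -2.38 ± 0.20 (adjusted p = 1.59e-05) and Ttk, a spindle checkpoint kinase, by -2.32 ± 0.23 (adjusted p = 3.33e-05), followed by the mitotic kinase gene Pbk (-2.32 ± 0.29), the centromere protein gene Cenpi (-2.30 ± 0.23) and the histone gene H3c15 (-2.30 ± 0.30). Gbp4 rose by 2.28 ± 0.21 (adjusted p = 2.54e-05), Gbp11 by 2.14 ± 0.15 (adjusted p = 8.23e-06), Gbp8 by 1.95 ± 0.17, Slfn5 by 1.78 ± 0.43, the anion transporter gene Slc22a8 by 1.74 ± 0.11 and Gbp9 by 1.73 ± 0.20. Of the 8 guanylate-binding protein genes, a family chosen after its values were seen, 4 rose and 2 fell.

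All 24 DNA replication genes and all 21 G2/M genes fell (24 and 21 adjusted over the list alone), with means of -1.49 and -1.83, among them Cdc45 (-1.88 ± 0.16), Mcm3 (-1.71 ± 0.15) and Bub1 (-2.09 ± 0.16). Camera gave adjusted p-values of 8.12e-27 and 8.72e-28, with an adjusted p of 0.244 and 0.24 with an estimated correlation. Ribosome biogenesis genes fell at 18 of 20 (19 adjusted over the list alone, camera adjusted p = 4.55e-17, or adjusted p = 0.249 with an estimated correlation), and Myc fell by 0.80 ± 0.11. Cholesterol and fatty acid synthesis genes fell at 10 of 17 (14 adjusted over the list alone), such as Idi1 (-1.24 ± 0.16). Lipid synthesis genes reached a camera adjusted p = 2.95e-08, or adjusted p = 0.321 with an estimated correlation. The IL-7 and STAT5 list fell at 5 of 15 and rose at 2 (5 and 2 adjusted over the list alone), with Ccnd2 (-1.79 ± 0.19), Socs2 (-1.53 ± 0.12) and Cish (-1.36 ± 0.09) lower. The IL-7 list reached a camera adjusted p = 0.00686, or adjusted p = 0.235 with an estimated correlation. Glycolysis genes fell at 8 of 16 (8 lower and 1 higher adjusted over the list alone), ATF4 genes fell at 6 of 14 and rose at 1 (7 and 1 adjusted over the list alone) and heat shock genes fell at 3 of 8 (3 adjusted over the list alone), with Hk2 at -1.11 ± 0.11 and Slc7a5 at -1.69 ± 0.16. These lists had camera adjusted p-values of 0.000688, 0.00235 and 0.0291, with an adjusted p of 0.435, 0.344 and 0.528 with an estimated correlation.

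Higher after 24 h without IL-7 and without 4OHT were FoxO targets, at 14 of 21 (17 adjusted over the list alone), with Bcl6 (1.65 ± 0.09) and Txnip (0.98 ± 0.12), and B lineage transcription factors, at 14 of 22 (16 adjusted over the list alone), with Spib (0.91 ± 0.10) and Irf8 (0.63 ± 0.07). Their camera adjusted p-values were 2.95e-08 and 1.11e-06, with an adjusted p of 0.249 and 0.24 with an estimated correlation. NF-kappaB response genes rose at 6 of 11 (6 adjusted over the list alone), such as Nfkbia (0.70 ± 0.09), pre-B cell receptor signalling at 5 of 12 (7 adjusted over the list alone), with Blnk at 0.76 ± 0.09, and small pre-B and later B cell markers at 6 of 19 (6 adjusted over the list alone). Camera gave adjusted p-values of 0.00328, 0.00614 and 0.0128, with an adjusted p of 0.24, 0.327 and 0.39 with an estimated correlation. Interferon response genes rose at 3 of 15, Oasl2 (1.15 ± 0.32), Ddx58 (0.94 ± 0.23) and Stat2 (0.41 ± 0.10) (3 adjusted over the list alone). Interferon genes had a camera adjusted p = 0.0198, or adjusted p = 0.685 with an estimated correlation. Of the 19938 genes 3982 passed limma's test, 2232 higher and 1750 lower, and 2279 without the array lacking IL-7 and 4OHT of experiment 2. The experiment as a block raised the passing members to 5 of 15 interferon response genes and to 7 higher and 1 lower of 12 pre-B cell receptor signalling genes. Without dim genes these lists and the heat shock list were not called (adjusted p of 0.118, 0.0721 and 0.0536), nor was heat shock after quantile normalization (adjusted p = 0.0781). Between IL-7 withdrawal at 6 h with 4OHT and at 24 h without it, which share no array, 834 genes rose in both against 151.4 for independent lists and 814 fell in both against 131 (Fisher's exact test, odds ratios 19.8 and 22.5, with r = 0.494 across genes). The difference between the 2 times was not tested.

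With 4OHT present, IL-7 withdrawal for 24 h lowered cell cycle genes as well, with larger falls in Myc and Srm. Srm changed by -3.67 ± 0.15 on the log2 scale (adjusted p = 6.31e-08), Ppa1 by -3.43 ± 0.19 (adjusted p = 2.85e-07), Dctd by -3.38 ± 0.12 (adjusted p = 2.82e-08), Myc by -3.27 ± 0.11 (adjusted p = 2.18e-08), the checkpoint kinase gene Chek1 by -3.23 ± 0.20 and Ccnd2 by -3.07 ± 0.19. Rises were smaller, with Klrb1 (1.48 ± 0.47), the nuclear GTPase gene Nuggc (1.26 ± 0.09), Adamtsl2 (1.25 ± 0.16), Pygm (1.21 ± 0.14), a glycogen phosphorylase, Bcl6 (1.20 ± 0.09) and Brwd1 (1.18 ± 0.14) the largest. Of the leading genes, Myc, Srm, Dctd, Ppa1 and Nuggc passed the interaction test, which is the same for IL-7 withdrawal with and without 4OHT.

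All 24 DNA replication genes, all 21 G2/M genes and all 20 ribosome biogenesis genes fell (24, 21 and 20 adjusted over the list alone), with means of -1.92, -1.70 and -1.53, among them Uhrf1 (-2.82 ± 0.19), Tyms (-2.56 ± 0.17), Cdk1 (-1.93 ± 0.16) and Nop58 (-1.78 ± 0.11). These lists had camera adjusted p-values of 1.83e-30, 2.19e-25 and 8.12e-27, with an adjusted p of 0.235, 0.244 and 0.235 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell at 11 of 17 (13 adjusted over the list alone), with Acaca at -1.42 ± 0.10. Lipid synthesis genes had a camera adjusted p = 1.34e-09, or adjusted p = 0.303 with an estimated correlation. Glycolysis genes fell at 7 of 16 (7 adjusted over the list alone), ATF4 genes fell at 7 of 14 and rose at 1 (7 and 1 adjusted over the list alone), heat shock genes fell at 4 of 8 and rose at 1 (4 and 1 adjusted over the list alone) and the IL-7 and STAT5 list fell at 6 of 15 and rose at 1 (6 and 2 adjusted over the list alone), with Slc7a5 at -2.67 ± 0.16 and Hspd1 at -1.85 ± 0.13. Their camera adjusted p-values were 1.82e-05, 0.000421, 0.00176 and 0.0017, with an adjusted p of 0.372, 0.303, 0.385 and 0.235 with an estimated correlation.

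FoxO targets rose at 15 of 21 under IL-7 withdrawal with 4OHT (16 adjusted over the list alone), with Foxo1 at 0.95 ± 0.12, B lineage transcription factors rose at 13 of 22 and fell at 1 (14 and 2 adjusted over the list alone), pre-B cell receptor signalling rose at 8 of 12 (8 adjusted over the list alone) and NF-kappaB response genes at 7 of 11 (7 adjusted over the list alone), with Birc3 at 0.79 ± 0.11. Camera gave adjusted p-values of 2.54e-06, 0.00277, 0.00248 and 0.00216, with an adjusted p of 0.298, 0.366, 0.303 and 0.235 with an estimated correlation. Light chain probes rose at 5 of 8 (5 adjusted over the list alone, camera adjusted p = 0.0318, or adjusted p = 0.255 with an estimated correlation), and small pre-B and later B cell markers at 6 of 19 (6 adjusted over the list alone). Small pre-B and later markers gave a camera adjusted p = 0.0367, or adjusted p = 0.453 with an estimated correlation. With 4OHT 4846 of 19938 genes passed limma's test, 2552 higher and 2294 lower, and the interferon response list, not called there (adjusted p = 0.146), was called higher with the experiment as a block (adjusted p = 0.0386). The light chain list was not called without dim genes (adjusted p = 0.118) or on the compared arrays only (adjusted p = 0.0502). Between IL-7 withdrawal without and with 4OHT, which share no array, 1688 genes rose in both against 285.7 for independent lists and 1540 fell in both against 201.3 (Fisher's exact test, odds ratios 60.4 and 170, with r = 0.847 across genes).

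**Figure D3:**
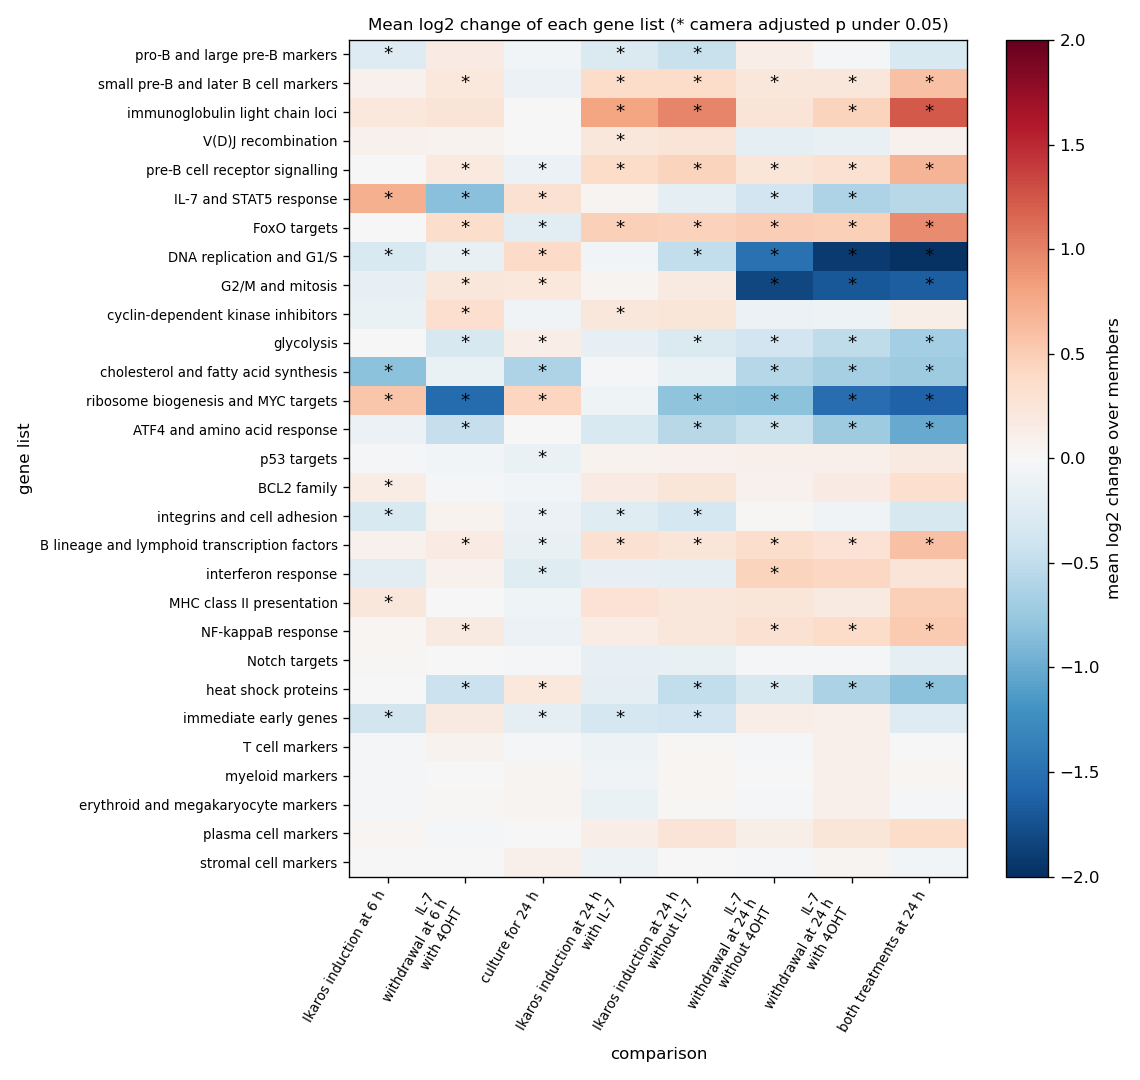
Mean log2 change over the members of each gene list (vertical axis) in 8 comparisons (horizontal axis), from blue for lower to red for higher, with a star where the camera adjusted p was under 0.05 at the preset correlation. The DNA replication and G2/M lists were lowest in the comparisons of IL-7 withdrawal at 24 h, down to -1.97 for DNA replication under both treatments.

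Both treatments together at 24 h, against IL-7 without 4OHT, gave the largest number of changed genes of the 9 comparisons. Klrb1 rose by 4.04 ± 0.47 (adjusted p = 2.33e-05), Cpm by 3.92 ± 0.24 (adjusted p = 1.87e-07), Eqtn by 3.56 ± 0.33 (adjusted p = 4.5e-06), Ifi209 by 3.26 ± 0.20, Spib by 2.97 ± 0.10 and the nuclear body gene Sp100 by 2.93 ± 0.32. Among 22 killer cell lectin-like receptors, a family chosen after its values were seen, Klrb1, Klrb1c (2.12 ± 0.33) and Klrb1a (0.86 ± 0.10) rose, 1 fell and 18 did not pass. Srm changed by -3.70 ± 0.15 on the log2 scale (adjusted p = 1.36e-08), Ppa1 by -3.63 ± 0.19 (adjusted p = 6.17e-08), Ccnd2 by -3.59 ± 0.19 (adjusted p = 7.87e-08), Myc by -3.50 ± 0.11, Dctd by -3.47 ± 0.12 and the lipase gene Smpdl3b by -3.44 ± 0.11. FoxO targets rose at 18 of 21 members (18 adjusted over the list alone), with S1pr1 at 2.89 ± 0.13 and Foxo1 at 1.77 ± 0.12, B lineage transcription factors rose at 16 of 22 and fell at 3 (16 and 3 adjusted over the list alone), and small pre-B and later B cell markers rose at 11 of 19 (11 adjusted over the list alone), with Cd22 at 0.95 ± 0.08. These lists had camera adjusted p-values of 2.61e-10, 2.71e-05 and 6.67e-05, with an adjusted p of 0.235, 0.255 and 0.255 with an estimated correlation. Pre-B cell receptor signalling rose at 9 of 12 (9 adjusted over the list alone), with Syk at 1.30 ± 0.10, light chain probes at 5 of 8 (5 adjusted over the list alone), with Igkv10-96 at 3.56 ± 0.24, and NF-kappaB response genes rose at 6 of 11 and fell at 1 (6 and 1 adjusted over the list alone), with Rel at 1.56 ± 0.10. Their camera adjusted p-values were 1.7e-05, 0.00153 and 0.0197, with an adjusted p of 0.235, 0.235 and 0.29 with an estimated correlation.

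Under both treatments all 24 DNA replication genes, all 21 G2/M genes and all 20 ribosome biogenesis genes fell (24, 21 and 20 adjusted over the list alone), with means of -1.97, -1.64 and -1.62. Camera gave adjusted p-values of 7.32e-20, 1.15e-15 and 9.05e-18, with an adjusted p of 0.29, 0.308 and 0.244 with an estimated correlation. Cholesterol and fatty acid synthesis genes fell at 12 of 17 (13 adjusted over the list alone), glycolysis genes at 10 of 16 (11 adjusted over the list alone) and heat shock genes at 5 of 8 (5 adjusted over the list alone), and ATF4 genes fell at 8 of 14 and rose at 1 (8 and 1 adjusted over the list alone), with Idi1 at -1.75 ± 0.16, Pgk1 at -1.79 ± 0.16 and Asns at -2.56 ± 0.19. These lists had camera adjusted p-values of 4.84e-06, 0.000126, 0.000854 and 0.000716, with an adjusted p of 0.372, 0.391, 0.372 and 0.308 with an estimated correlation. The IL-7 and STAT5 list had 5 members higher and 7 lower of 15 (adjusted p = 0.155) and was not called. Of the 19938 genes 6690 passed limma's test, 3614 higher and 3076 lower, and the split was 3310 higher and 4413 lower after quantile normalization.

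Effects at 6 h and 24 h were compared only where no array was shared. Between 6 h of culture with 4OHT against time 0, where culture and 4OHT are not separated, and 4OHT at 24 h with IL-7, 196 genes rose in both against 40.8 for independent lists and 422 fell in both against 38.1 (Fisher's exact test, odds ratios 7.26 and 39.7, with r = 0.424 across genes). Between IL-7 withdrawal at 24 h without 4OHT and 6 h of culture with 4OHT against time 0 the calls overlapped in all directions beyond independent lists, and most in opposite ones, with 358 genes higher in the first and lower in the second against 108.3, and 290 the other way round against 68.6 (Fisher's exact test, odds ratios 5.36 and 7.16, with r = -0.14). In the same direction, 137 were higher in both against 87.4 and 104 lower in both against 84.9 (odds ratios 1.73 and 1.27). Each gene's spread is shared by the comparisons, which alone can raise overlaps in every direction, so small excesses are not read as shared regulation. Between IL-7 withdrawal at 6 h and 4OHT at 24 h with IL-7, 392 genes rose in both against 70.6 for independent lists and 89 fell in both against 58.7 (Fisher's exact test, odds ratios 11.3 and 1.62, with r = 0.161). Of opposite calls in this pair, 126 genes were higher in the first and lower in the second against 53.2, and 33 the other way round against 77.9 (odds ratios 2.8 and 0.391). Across all comparisons 107 of 261 list tests were called at camera's preset correlation, and 2 of these held with an estimated correlation, the IL-7 and STAT5 response at 6 h with 4OHT against time 0 and at 6 h of IL-7 withdrawal. In each of the 107 the list's median, mean and test had the same sign, and 91 also passed fry, which asks whether a list's genes moved one way on balance.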

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

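In this part, the tests of 4OHT as the whole cause, of array normalization at 6 h and of a smaller share of dividing cells were chosen after the results were seen, as was the spread used to judge the level-matched test.

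The 4OHT effect at 24 h differed between cells with and without IL-7 at 137 genes by limma's interaction test. Values are the effect without IL-7 minus the effect with it. They were 1.24 for Adgrg1, 1.23 for Nuggc, 1.14 for Tfrc, 1.12 for Cd248, 1.11 for S100a10 and 0.92 for Zfp831. They were -2.47 for Myc, -2.37 for Srm, -2.16 for Dctd, -1.66 for Nrp2, -1.62 for Ppa1, -1.59 for Vegfa, -1.48 for Polr1b, -1.07 for Hsph1, -0.82 for Nolc1, -0.77 for Polr1a and -0.75 for Vpreb1. The mean over list members was -0.71 for ribosome biogenesis and MYC targets, -0.43 for DNA replication, -0.31 for heat shock proteins, -0.26 for ATF4 and amino acid response, -0.24 for the IL-7 and STAT5 response, -0.16 for pro-B and large pre-B markers and -0.13 for glycolysis. The adjusted p of these 7 list tests was between 0.235 and 0.617 with an estimated correlation. Probe sets with several gene symbols or none are not used in the comparisons by gene. Of these, 2926 of 13767 changed under both treatments at 24 h, 2003 higher and 923 lower. The median of all probes was 7.28 at 24 h with IL-7 and no 4OHT and 7.38 under both treatments. For named genes quantile normalization turned the majority of changes in this comparison from higher to lower. It was not checked for these probe sets, so their split is uncertain. In the other comparisons 38 (24 h of culture) to 864 (IL-7 withdrawal at 24 h with 4OHT) changed. In the interaction 0 changed by limma. There 590 had an unadjusted p under 0.05, a smaller share of the 13767 than the 0.05 that no change would give.

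The interaction was negative for Myc and for the ribosome biogenesis list, where 4 of 20 members passed and the list call was lost with an estimated correlation (adjusted p = 0.235). Saturation with IL-7 would hide a fall there. Of the 21 genes 0% lay above the 99th percentile of those arrays (13.21), and the highest member had a mean of 12.87. That percentile is not a saturation level, and the limit of saturation was not read from the arrays, so this does not exclude saturation. If normalization depended on signal level, genes of like level would share the interaction, within 0.2 of 0. The list's median differed by -0.529 (bootstrap SE 0.104) from that of the 500 genes nearest in level. That value passed the bound of -0.5 set beforehand by less than 1 SE and lay more than 2 SE outside 0.2. This bootstrap SE is over list members, which share arrays, and does not measure the spread between experiments. A smaller share of dividing cells would lower the G2/M list as well, whose mean interaction was 0.127. Its SE of 0.035 is over list members, which share arrays and are not replicates. Without IL-7 the list's mean level was 9.59 without 4OHT and 9.77 with it, well above the 5th percentile of 4.48. The DNA replication list had a mean of -0.43, so a shift in S phase stays open. As a hypothesis, a joint effect on Myc of IL-7 loss with Ikaros activity, or with 4OHT itself, stays open too.

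IL-7 response genes such as Cish and Socs2 rose from time 0 to 6 h with 4OHT although IL-7 was kept. 4OHT or Ikaros activity as the whole cause would leave the IL-7 and STAT5 list at its time 0 level in cells without 4OHT. The list was instead higher by 0.298 after 24 h of culture, with an SE of 0.14 over list members, which are not replicates. Cish, Socs2 and Ccnd2 passed there. Normalization that depended on signal level would leave the list's median change at 6 h within 0.2 of that of genes of like level. It lay 0.692 (bootstrap SE 0.165) above that of the 500 genes nearest in level, which argues against normalization as the whole cause. This bootstrap SE is over list members too and does not measure the spread between experiments. Weaker IL-7 signalling in the time 0 cells than in cells later kept in IL-7 is a candidate explanation, since of the 200 genes with the largest changes at 6 h of IL-7 withdrawal 98.5% (197) went the opposite way from time 0 to 24 h of culture with IL-7, in arrays with none in common, and r over all genes was -0.536. Cholesterol and fatty acid synthesis genes did not reverse in this way. Their list was called lower at camera's preset correlation both over 24 h of culture and after 24 h of IL-7 withdrawal. No measurement of IL-7 signalling is among the data used here, and an added effect of 4OHT at 6 h stays open.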

How the results depend on the processing

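The 24 h arrays as reference and the fits without time 0 were chosen after the data were seen. With the experiment as a replicate block the gene counts were 2999 for 6 h with 4OHT, 2056 for 24 h of culture, 3324 for 4OHT at 24 h with IL-7 and 449 for the interaction; the other 5 counts stayed within 1.5-fold, all calls without the block were kept, and no list call changed beyond the 8 given with their comparisons. A minimum of 1.5-fold left, by construction, 648 genes for 6 h with 4OHT, 955 for IL-7 withdrawal at 6 h, 171 for culture, 675 and 1219 for 4OHT at 24 h with and without IL-7, 1271 and 1608 for IL-7 withdrawal at 24 h without and with 4OHT, and 3169 for both treatments. On the compared arrays only, with fewer arrays to estimate the spread, 884 genes passed for 6 h with 4OHT and 128 for culture. Leaving out 1 array, with the lone array assumed to vary like the other groups, gave 1067 to 1344 genes for 6 h with 4OHT, 1490 to 2336 for IL-7 withdrawal at 6 h, 39 to 745 for culture, 847 to 1700 and 1841 to 2282 for 4OHT at 24 h with and without IL-7, 2279 to 3252 and 3257 to 4014 for IL-7 withdrawal at 24 h without and with 4OHT, 50 to 96 for the interaction and 5752 to 5988 for both treatments. The dim-gene filter, the variance model, the mean of probes and quantile normalization moved none of the 9 counts by over 1.5-fold, nor did leaving out the time 0 arrays. With the 24 h reference for 6 h with 4OHT, Ccnd2 changed sign to -0.297, which did not pass in limma (adjusted p = 0.411). The heat shock list was called lower at -0.221 (camera adjusted p = 0.00842). For Ccnd2 the sign follows from the reference, as its mean was 10.915 at time 0, 11.979 at 6 h and 12.276 in the 24 h arrays. The heat shock list was likewise higher in the 24 h arrays than at time 0. Under that reference 7 named genes (Socs2 at 0.277 and Myc at 0.37 among them) and the immediate early list no longer passed, and 5 named genes and 6 lists passed that had not, such as FoxO targets (0.223). An estimated correlation, which also leaves camera fewer degrees of freedom, ended 105 of 107 list calls (camera adjusted p from 0.235 to 0.762). The dim-gene filter ended 22 and added 4, and the compared arrays only ended 5 and added 5. Quantile normalization ended 4 and added 6, and the mean of probes ended 1 and added 2. The calls that these 4 settings ended stand with their comparisons. The filter left fewer genes to compare with, and the other causes were not tested. Of 642 named gene results, 33 no longer passed on the compared arrays only and 8 newly passed, against 5 and 13 after quantile normalization and 2 and 6 with the variance model. Leaving out 1 array ended 210 named gene calls, counted once per array left out, with 50 in culture and 50 in the interaction, and added 32. Genes near the floor of the arrays, such as Rag1 and Rag2, have little signal over background, which limits what a missing call says.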

Other observations

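The families in this part were chosen after their values were seen, and none of their called members changed sign under quantile normalization.

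Probes that carry the symbols of the Mir17 cluster (Mir17hg, Mir17, Mir18, Mir19a, Mir19b-1 and Mir20a), a microRNA cluster known as a target of MYC, moved together. All 6 rose at 6 h with 4OHT and IL-7 against time 0 (mean 1.55), and 4 of the 6 also rose over 24 h of culture without 4OHT (mean 0.92). All 6 fell at 6 h of IL-7 withdrawal (mean -1.90), as did all 6 at 24 h of withdrawal with 4OHT (mean -1.42) and 4 of 6 at 24 h without 4OHT (mean -0.74). Under both treatments all 6 fell (mean -1.44). With IL-7 at 24 h, 0 of 6 passed limma's test under 4OHT, with 0 at an unadjusted p under 0.05 and 0 passing with the experiment as a block, while 4 fell without IL-7 (mean -0.70). The interaction passed limma's test for 0 of 6 (mean -0.67), with 4 at an unadjusted p under 0.05 and 2 passing with the block. The 6 probes read neighbouring parts of 1 primary transcript and are not independent. The cytosolic aminoacyl-tRNA synthetases, enzymes that charge transfer RNAs, fell at 14 of 18 members at 6 h of IL-7 withdrawal (mean -0.56) and at 13 and 16 of 18 at 24 h without and with 4OHT (means -0.50 and -0.62). Under both treatments 16 fell. Under 4OHT at 24 h without IL-7, 4 of the 18 fell and 1 rose (9 and 1 after quantile normalization, 11 and 1 with the block). At 6 h with 4OHT against time 0, 3 rose and 1 fell (5 and 1 with the block). In limma 0 of 18 passed for 4OHT at 24 h with IL-7, for culture and for the interaction, with 3, 6 and 0 at an unadjusted p under 0.05 and 0, 2 and 0 with the block.

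Guanylate-binding proteins did not move as 1 group. At 6 h with 4OHT against time 0, 4 of 8 fell and 2 rose, and 4 fell and 2 rose over 24 h of culture. After 24 h without IL-7, 4 rose and 2 fell without 4OHT, and 4 rose and 1 fell with it. Under 4OHT at 24 h 3 fell with IL-7 and 4 without. Under both treatments 4 fell (4 lower and 2 higher with the block), and at 6 h of IL-7 withdrawal 2 fell (2 lower and 1 higher with the block). The interaction passed for 1 of 8, and for 3 with the block, all lower. At an unadjusted p under 0.05 in limma, 4 were lower and 1 higher there. The 27 replication-dependent histone genes and the 14 condensin and cohesin genes each had 2 members higher at 6 h of IL-7 withdrawal (3 and 6 with the block). At 24 h of withdrawal 17 of the histone genes and 11 of the condensin and cohesin genes fell without 4OHT, and 19 and 11 with it. The difference between the times was not tested. At 6 h with 4OHT against time 0, 4 of each fell (6 and 7 with the block). Fanconi anaemia genes fell at 7 of 10 members at 24 h without IL-7 and without 4OHT and at 8 of 10 with 4OHT, while at 6 h of withdrawal 2 rose and 1 fell.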
